A study of Mus musculus with 6 samples.

How the data were processed

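Ovaries of ICR mice, an outbred strain, were profiled by bulk RNA sequencing in 6 libraries: 2 from a group labelled COH, 2 from a mouse model of ovarian hyperstimulation syndrome (OHSS), and 2 from OHSS mice that received nintedanib. The deposited table holds raw whole-number counts for 51826 Ensembl gene IDs in each library, per the file headers, with symbols and pathway annotation beside each ID, and no row lacks a gene. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, StringTie 1.3.3b and the genome build mm8, without saying which tool did what. The program that counted the reads, the annotation release, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Reads of genes with near-identical copies, of overlapping genes and of antisense partners therefore could have been split or lost in a way that cannot be seen from the table, and such genes are given as uncertain. Deposited read summaries per library list 38504916 to 47163764 reads with mean lengths of 143.7 to 144.1 bases, 93.4 to 94.0% of bases at quality 30 and a GC share of 48.8 to 49.3%. The gene counts come to 144.2 to 148% of the number of read pairs but 72.1 to 74.0% of the number of reads, so a pair appears to have been counted as 2 reads, and the counting error of a gene is larger than its count alone would give. For genes with a group near 0, 2 counts are therefore taken as 1 pair. A fold against a group with no counts is a bound at a floor of 3 pairs or 6 counts per library, and 1 with a single count is a ratio with its exact Poisson interval, both for counting error only.

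Total counts were 34716751 and 28609601 in COH, 32390829 and 30993703 in OHSS and 28498435 and 31308357 with nintedanib. Group and replicate number came from the sample titles, and the 3 comparisons were OHSS against COH, OHSS with nintedanib against OHSS, and OHSS with nintedanib against COH. Genes with low counts were removed with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 19027 genes, and libraries were scaled with TMM factors of 0.961 to 1.03. The test was edgeR's two-sided quasi-likelihood F test in 1 fit of the 3 groups, which leaves 3 residual degrees of freedom beside 2.41 prior degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, with no fold threshold. The standard error of a log2 fold change was derived from the F statistic, and group levels are CPM (counts scaled to a common effective library size) with the SD of 2 libraries. An exact permutation test of 2 libraries against 2 cannot reach a two-sided p below 0.333, so none is given. Nothing in the labels says that the libraries of a group came from separate animals, and the p-values then measure only the spread between these samples, which may be technical.

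A set of 29 gene lists with 415 genes was fixed for pathways and cell types that fit the ovary, its vessels and the drug, and 1 of these genes has no row in the table. The mitochondrial transcripts and the immediate early and heat shock genes were listed as signs of RNA quality and handling. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list's genes rank above or below the other genes tested. The same test with an estimated correlation and the fry test were run beside it, and calls among the members of a list were also adjusted over the list alone. The fold changes of the first 2 comparisons share the OHSS libraries, so their correlation and their share of opposite signs, and the overlap of their genes and lists, were set beside 20 simulated data sets in which no group differs.

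Genes named in the text follow a rule. It takes, per comparison, up to 10 genes with the largest rise and up to 10 with the largest fall among those called, with a mean of at least 5 CPM, groups that do not overlap and no predicted, clone or pseudogene name. It adds Vegfa, Kdr, Flt1, Flt4, Pdgfra, Pdgfrb, Fgfr1, Fgfr2, Fgfr3, Pecam1, Cdh5, Star, Cyp11a1, Cyp17a1, Cyp19a1 and Lhcgr whatever their p, and up to 4 members with the smallest p of each list described. Other genes are named as chosen after their values were seen. Not all of the list members that the rule allows are named, and the result of 1 of its genes is not reported here. The grouping, the test, the lists, the naming rule and the following alternatives were set before the data were examined: other scalings (RLE, upper quartile, library size only), no filter or a stricter one, DESeq2 1.42.0, limma voom, a replicate block, a fit of only the 2 groups compared, a fold threshold and each library left out in turn. A fit with a robust prior and the DESeq2 versions of the opposite-sign share and of the correlation were added after the data had been seen, as was the test of the pathways in the table's own annotation. For a comparison that does not hold the library left out, the refit changes the filter, the scaling, the estimated spread and the residual degrees of freedom. A call lost in that way does not rest on the level of the gene in that library.

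The box reference is GENCODE release 21 for mouse on assembly GRCm38, a later build than mm8. No coordinates are therefore given, and the reference served only for names, for which genes lie near each other and for transcript sequence and length. It holds 51633 of the IDs, 47551 of them with the same symbol. The test was checked on simulated data drawn from the libraries' own means and spreads, with 50 genes changed at each of 4 sizes. For OHSS against COH (18596 genes) it called 8% of the genes changed 2-fold, 74% at 4-fold, 84% at 8-fold and 98% at 16-fold, and 15 unchanged genes. The shares were 8, 68, 90 and 92% for nintedanib against OHSS (18583 genes, 10 unchanged genes called) and 6, 70, 88 and 96% for nintedanib against COH (18590 genes, 10 unchanged genes called). Many genes were changed in each simulated data set, which eases the adjusted threshold, while the real comparisons had few calls. The shares may therefore be too high for the real data. The 15 unchanged genes called for OHSS against COH stand beside 4, 37, 42 and 49 changed genes called. In each comparison unchanged genes made up more of the calls than an adjusted p of 0.05 aims for. With a single simulated data set per comparison this may be chance, but the called genes may hold more false calls than the threshold states. A simulated list changed 1.5-fold had a camera adjusted p of 1.61e-13 for OHSS against COH, 4.15e-10 for nintedanib against OHSS and 8.78e-08 for nintedanib against COH. With an estimated correlation the same lists had a camera adjusted p of 0.097, 0.207 and 0.564, so the estimated version missed a change of that size here. The preset version also called 0, 1 and 0 of the unchanged lists. The simulation draws genes independently, without the correlation of real list members. It therefore cannot show how often the preset version calls unchanged lists in real data.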

Results

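Ovarian RNA was measured in 3 groups of 2 mouse libraries. In ovarian hyperstimulation syndrome, hormone stimulation leads to enlarged ovaries and leaky vessels, a process in which vascular endothelial growth factor (VEGF) takes part. The first group carries the name COH, which the labels do not spell out, and served here as the reference for the OHSS model. Nintedanib, given to the last group, inhibits the kinases of the VEGF, platelet-derived growth factor and fibroblast growth factor receptors. Total counts ranged from 28498435 to 34716751 per library, and 24712 to 25796 genes had at least 1 count. Mitochondrial transcripts took 5.21 and 5.96% of counts in the COH libraries, 6.80 and 7.10% in OHSS and 5.88 and 5.72% with nintedanib.

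OHSS against COH asks which ovarian transcripts differ in the syndrome model. Genes of cholesterol synthesis and uptake rose in OHSS, with higher means for 21 of 21 measured members and a median log2 fold change of 0.88 (camera adjusted p = 4.68e-17, and adjusted p = 0.567 with an estimated correlation). Insig1, a sterol-responsive regulator of the pathway, averaged 198.7 ± 6.83 CPM in OHSS and 90.3 ± 10.5 CPM in COH (SD, n = 2), a log2 fold change of 1.14 (SE 0.116). Idi1, an isomerase that supplies isoprenoid precursors, stood at 255 ± 27.0 against 103.3 ± 14.1 CPM. Msmo1, a sterol demethylation enzyme, differed by 0.99 (SE 0.117). The median of the list lay 0.91 and 0.83 above the COH mean in the 2 OHSS libraries. Of the 21 members, edgeR called 0 over all genes, 17 adjusted over the list alone and 17 at an unadjusted p under 0.05, while DESeq2 called 14 and limma voom 0.

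Tmem170b and Ak4 rose in OHSS. Tmem170b (ENSMUSG00000087370), which encodes a transmembrane protein, stood at 45.8 ± 4.55 CPM in OHSS and 1.21 ± 0.121 CPM in COH (SD, n = 2), a log2 fold change of 5.24 (SE 0.173, edgeR adjusted p = 0.00568). Ak4 (ENSMUSG00000028527), a mitochondrial adenylate kinase, stood at 14.3 ± 0.613 against 1.61 ± 0.00643 CPM, a log2 fold change of 3.15 (SE 0.166, edgeR adjusted p = 0.0356). Both OHSS libraries lay above both COH libraries for each gene. These 2 genes were the only ones of 19027 called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 2 higher and 0 lower. At an unadjusted p under 0.05 there were 1679 genes, 873 higher and 806 lower, where 951 would be expected by chance. The groups did not overlap for 44.1% of genes, against 33.3% by chance. Genes of a library do not vary independently, so in each comparison an excess over these chance values does not by itself show a group effect. DESeq2 called 348 genes, 226 higher and 122 lower, and limma voom called 0, with 1585 at an unadjusted p under 0.05. Without COH replicate 1, COH replicate 2, OHSS replicate 2, nintedanib replicate 1 or nintedanib replicate 2 edgeR called 0 genes, with 1078, 839, 1702, 1897 and 1898 at an unadjusted p under 0.05. Without OHSS replicate 1 it called 2, Tmem170b among them and Ak4 not. The edgeR adjusted p of Tmem170b was 0.144, 0.269, 0.0658, 0.0517 and 0.0521 without those 5 libraries in that order (range with each library left out 0.029 to 0.269), and that of Ak4 0.287, 0.342, 0.131, 0.105 and 0.105, and 0.127 without OHSS replicate 1 (range 0.105 to 0.342). Their log2 fold changes stayed between 5.13 and 5.35 and between 3.12 and 3.18.

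Interferon response genes rose in OHSS, with higher means for 14 of 14 measured members and a median log2 fold change of 3.51 (camera adjusted p = 5.03e-08, and adjusted p = 0.59 with an estimated correlation). Oasl2, of the antiviral oligoadenylate synthetase family, reached 108.4 ± 54.2 CPM against 23.0 ± 0.69 CPM in COH (SD, n = 2), a log2 fold change of 2.24 (SE 0.364). Usp18, a brake on interferon signalling, reached 54.99 ± 60.6 against 2.03 ± 0.249 CPM, and Oas1a 16.3 ± 16.1 against 1.41 ± 0.112 CPM. The 2 OHSS libraries differed widely here, with list medians 4.37 and 1.76 above the COH mean. Of the 14 members, edgeR called 0 over all genes, 10 adjusted over the list alone and 11 at an unadjusted p under 0.05, DESeq2 called 7 and limma voom 0. Without OHSS replicate 1 the interferon median was 1.77. Inflammatory cytokines and adhesion molecules rose, with 12 of 16 members higher and a median of 0.23 (camera adjusted p = 0.0159, and adjusted p = 0.59 with an estimated correlation). Sele, the endothelial E-selectin, had a log2 fold change of 1.89 (SE 0.378) at only 1.34 ± 0.255 CPM, and Cxcl10, a chemokine that interferon induces, 2.80 (SE 0.908). The inflammatory call was lost without COH replicate 1 (camera adjusted p = 0.358), OHSS replicate 1 (0.175) or OHSS replicate 2 (0.0711), and spanned 0.00689 to 0.358 over the alternatives at the preset correlation. Of its 16 members edgeR called 0 and limma voom 0, with 3 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 2. Its median was 0.51 without COH replicate 2 and 0.35 without OHSS replicate 2.

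Endothelial cell markers fell in OHSS, with lower means for 16 of 20 members and a median log2 fold change of -0.24 (camera adjusted p = 0.00143, and adjusted p = 0.567 with an estimated correlation). Cldn5, the tight junction claudin of endothelium, averaged 46.9 ± 4.55 CPM in OHSS and 73.1 ± 0.193 CPM in COH (SD, n = 2), a log2 fold change of -0.64 (SE 0.121). Tie1, an endothelial receptor kinase, and Ecscr, an endothelial surface protein, differed by -0.34 (SE 0.101) and -0.46 (SE 0.154). Of the 20 members, edgeR called 0 over all genes, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. Endothelial tip and sprouting genes fell, with 12 of 16 lower and a median of -0.17 (camera adjusted p = 0.0481, and adjusted p = 0.703 with an estimated correlation), among them Unc5b, a guidance receptor, at -0.45 (SE 0.165). That call was lost without COH replicate 1 (camera adjusted p = 0.125), COH replicate 2 (0.066), OHSS replicate 1 (0.0829) or OHSS replicate 2 (0.185), and spanned 0.0447 to 0.185 over the alternatives. The endothelial median was -0.36 without OHSS replicate 2 and the tip median -0.28 without OHSS replicate 1. Of the 16 tip genes edgeR had 1 at an unadjusted p under 0.05, and edgeR, DESeq2 and limma voom called 0. Vessel barrier genes (median -0.25, camera adjusted p = 0.198, with 1 member, Cldn5, called when adjusted over the list alone), VEGF and angiopoietin ligands and receptors (-0.09, 0.362), the target kinases of nintedanib (-0.09, 0.243) and lymphatic endothelial markers (-0.13, 0.421) were not called. With 1 library left out the vessel barrier median was -0.0058 without OHSS replicate 1 and otherwise moved little, and the other 3 medians ran from -0.10 to -0.04, -0.21 to -0.02 and -0.26 to -0.0032.

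Vegfa, the main VEGF ligand, stood at 138.9 ± 39.3 CPM in OHSS and 96.3 ± 9.33 CPM in COH (SD, n = 2), a log2 fold change of 0.53 (SE 0.212) that was not called (edgeR adjusted p = 0.568). Its receptors Kdr, Flt1 and Flt4 differed by -0.11 (SE 0.131), 0.15 (SE 0.146) and -0.08 (SE 0.142). The platelet-derived growth factor receptors Pdgfra and Pdgfrb differed by -0.08 (SE 0.159) and -0.33 (SE 0.248), and the fibroblast growth factor receptors Fgfr1, Fgfr2 and Fgfr3 by -0.06 (SE 0.183), 0.26 (SE 0.295) and -0.10 (SE 0.459). The endothelial adhesion molecules Pecam1 and Cdh5 differed by -0.20 (SE 0.202) and -0.25 (SE 0.129). None of these 11 genes was called by edgeR, DESeq2 or limma voom.

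Steroid hormone synthesis genes rose in OHSS, with 14 of 17 members higher and a median log2 fold change of 0.37 (camera adjusted p = 0.0177, and adjusted p = 0.59 with an estimated correlation). Star, which brings cholesterol into mitochondria, averaged 2059 ± 938 CPM in OHSS and 878 ± 20.9 CPM in COH (SD, n = 2), a log2 fold change of 1.23 (SE 0.338). Cyp17a1, the androgen-forming enzyme of theca cells, stood at 1048 ± 258 against 336.4 ± 173 CPM (log2 1.64, SE 0.656), and Cyp19a1, the aromatase of granulosa cells, at 40.3 ± 1.75 against 22.6 ± 6.84 CPM (0.83, SE 0.366). Cyp11a1, which starts steroid synthesis from cholesterol, and the luteinizing hormone receptor Lhcgr differed by 0.19 (SE 0.186) and 0.12 (SE 0.337). Luteal cell markers rose, with 10 of 12 higher and a median of 0.35 (camera adjusted p = 0.0405, and adjusted p = 0.59 with an estimated correlation), Star and Sfrp4 among them, the latter at 0.77 (SE 0.295). The luteal and steroid lists share members, Star, Cyp11a1 and Lhcgr among them, so their calls are not separate evidence. Oocyte markers fell, with 17 of 18 lower and a median of -0.50 (camera adjusted p = 0.00638, and adjusted p = 0.734 with an estimated correlation), for example Figla, an oocyte transcription factor, at -1.17 (SE 0.515) and Zp3, an egg coat protein, at -0.56 (SE 0.287). Without COH replicate 1 the steroid, luteal and oocyte lists lost their calls (camera adjusted p = 0.108, 0.262 and 0.405), and so did the steroid and oocyte lists without OHSS replicate 1 (0.175 and 0.13) and the luteal list without OHSS replicate 2 (0.136). Over the alternatives their adjusted p spanned 0.0107 to 0.175, 0.028 to 0.262 and 1.81e-05 to 0.405. The luteal median was 0.55 without COH replicate 2 and 0.20 without OHSS replicate 2, and the oocyte median -0.13 without COH replicate 1 and -0.78 without COH replicate 2. Of the steroid, luteal and oocyte members edgeR had 1, 2 and 0 at an unadjusted p under 0.05, DESeq2 called 1, 1 and 0, and edgeR and limma voom called 0 over all genes.

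Mitochondrial transcripts rose in OHSS, with 12 of 13 higher and a median log2 fold change of 0.34 (camera adjusted p = 9.33e-06, and adjusted p = 0.59 with an estimated correlation). The ATP synthase subunit mt-Atp8 differed by 0.48 (SE 0.135). Its neighbour mt-Atp6 stood at 5394 ± 84.4 CPM against 899.8 ± 138 CPM in COH (SD, n = 2), a log2 fold change of 2.58 (SE 0.195), but was not called over all genes (edgeR adjusted p = 0.084) and was the 1 member called when adjusted over the list alone. The annotated mt-Atp6 transcript shares 678 of 678 aligned bases with the nuclear copy Gm10925, so their reads cannot be separated by sequence and both levels are uncertain. Immediate early and heat shock genes fell, with 12 of 13 lower and a median of -0.68 (camera adjusted p = 0.00149, and adjusted p = 0.68 with an estimated correlation). The early growth factor responders Ier2, Fosb and Fos differed by -0.93 (SE 0.22), -2.08 (SE 0.638) and -2.07 (SE 0.657). Erythroid markers fell, with 5 of 5 lower and a median of -0.86 (camera adjusted p = 0.0177, and adjusted p = 0.649 with an estimated correlation), for example the globin Hbb-bt at -0.80 (SE 0.338). The immediate early call was lost without OHSS replicate 1 (camera adjusted p = 0.125, range over the alternatives 1.92e-05 to 0.125), and the erythroid call without COH replicate 1 (0.108) or OHSS replicate 1 (0.284, range 0.000328 to 0.284). At an unadjusted p under 0.05 edgeR had 5 mitochondrial, 3 immediate early and 0 erythroid genes, with 0 called over all genes by edgeR or limma voom, and DESeq2 called 1, 3 and 0. The mitochondrial and immediate early lists had been fixed as signs of RNA quality and handling. Both were called here together with 9 pathway and cell type lists. The mitochondrial median was 0.22 without COH replicate 1. The erythroid medians of the OHSS libraries were -1.74 and -0.29, and the median log2 fold change was -0.27 without OHSS replicate 1 and -1.75 without OHSS replicate 2.

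The lists not called in OHSS against COH covered other cells and processes. Ovulation and cumulus expansion genes had 12 of 18 members higher and a median log2 fold change of 0.25 (camera adjusted p = 0.243). Pgr, the progesterone receptor that ovulation needs, stood at 15.0 ± 1.22 against 3.57 ± 0.751 CPM (SD, n = 2; log2 2.08, SE 0.224), and Ptx3, a matrix protein of the cumulus, at 1.44 ± 0.211 against 4.93 ± 0.978 CPM (-1.78, SE 0.312). These were the 2 members called by edgeR when adjusted over the list alone. Medians and camera adjusted p were 0.06 and 0.76 for granulosa cell markers, -0.20 and 0.274 for stromal and theca markers, 0.16 and 0.179 for pericyte and smooth muscle markers, and -0.49 and 0.139 for ovarian surface epithelium markers. For oviduct epithelium markers they were 0.70 and 0.105, for adipocyte markers 0.24 and 0.319, for macrophage and monocyte markers 0.15 and 0.809, for neutrophil markers 0.02 and 0.668, and for lymphocyte markers -0.45 and 0.105. For cell cycle genes they were -0.05 and 0.171, for hypoxia response genes -0.04 and 0.668, for extracellular matrix and fibrosis genes -0.07 and 0.319, and for renin angiotensin and kinin genes 0.18 and 0.809. The median and the camera direction differed in sign for the neutrophil and hypoxia lists. With 1 library left out these medians moved widely, from -0.10 to 0.29 for granulosa, -0.37 to -0.016 for stromal and theca, 0.13 to 0.23 for pericyte, -0.93 to -0.12 for surface epithelium, 0.18 to 1.07 for oviduct and -1.27 to 1.23 for adipocyte markers. For macrophage, neutrophil and lymphocyte markers they ran from -0.16 to 0.37, -1.03 to 0.42 and -0.70 to -0.25, and for ovulation and cell cycle genes from 0.11 to 0.33 and -0.27 to 0.10. For hypoxia, extracellular matrix and renin angiotensin genes they ran from -0.20 to 0.097, -0.14 to 0.0067 and -0.029 to 0.12. The sign turned without OHSS replicate 2 for granulosa, neutrophil, adipocyte, cell cycle, hypoxia and renin angiotensin, without COH replicate 2 for granulosa, neutrophil and extracellular matrix, without OHSS replicate 1 for macrophage and without COH replicate 1 for adipocyte markers. Some of these lists were called as lower by camera with a library left out: lymphocyte markers without COH replicate 1 or either nintedanib library, cell cycle genes without COH replicate 2 or OHSS replicate 1, surface epithelium without COH replicate 2 or OHSS replicate 2, stromal and theca without OHSS replicate 1 and neutrophil without OHSS replicate 2. Of the 29 lists, 11 were called, 6 higher and 5 lower, and 0 were called with an estimated correlation or by the directional fry test. The mixed fry test, which asks for change in either direction without comparing with other genes, called 5: vessel barrier (fry adjusted p = 0.0151), cholesterol (0.00903), ovulation (0.00903), inflammatory (0.014) and mitochondrial (0.014). Over the 364 tested genes of all lists edgeR called 0 and limma voom 0, with 66 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 33, 28 of them higher. The cholesterol, interferon, mitochondrial and endothelial lists kept their calls with each library left out in turn. Without COH replicate 1 the number of lists called was 6 and without OHSS replicate 1 it was 7.

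OHSS with nintedanib against OHSS asks what the drug changed in the model. Nintedanib replicate 2 stands apart from the rest, at 83.5 on the first principal component (31.9% of the variance) against -38 to 7.41 for the other 5 libraries. Nor did the other libraries all group by condition in Spearman correlations of log2 CPM. OHSS replicate 1 was closer to nintedanib replicate 1 (0.979) than to OHSS replicate 2 (0.9752). OHSS replicate 2 was closer to COH replicate 1 (0.9782) than to OHSS replicate 1. Nintedanib replicate 1 was closer to OHSS replicate 1 than to nintedanib replicate 2 (0.9689). The 2 COH libraries were closest to each other (0.9821). Cell cycle genes rose with nintedanib, with higher means for 23 of 23 members and a median log2 fold change of 0.42 (camera adjusted p = 1.94e-08, and adjusted p = 0.525 with an estimated correlation). Ccnb1, the mitotic cyclin, averaged 33.9 ± 2.73 CPM with nintedanib and 20.7 ± 0.334 CPM in OHSS (SD, n = 2), a log2 fold change of 0.71 (SE 0.121). Bub1b, a spindle checkpoint kinase, and Mcm6, a replication helicase subunit, differed by 0.63 (SE 0.188) and 0.52 (SE 0.157). Granulosa cell markers rose, with 14 of 14 higher and a median of 0.54 (camera adjusted p = 2.39e-05, and adjusted p = 0.525 with an estimated correlation). The inhibin and activin subunit Inhba stood at 716.5 ± 251 against 330.2 ± 83.9 CPM (log2 1.12, SE 0.309), Inha differed by 0.56 (SE 0.159) and Nr5a2, a nuclear receptor of granulosa cells, by 0.75 (SE 0.185). Over all genes edgeR called 0 members of either list and limma voom 0. At an unadjusted p under 0.05 edgeR had 10 of the cell cycle and 6 of the granulosa genes, adjusted over the list alone 1 and 0, and DESeq2 called 1 and 0. Without OHSS replicate 2 the cell cycle median was 0.27.

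Cholesterol synthesis and uptake genes fell with nintedanib, with lower means for 20 of 21 members and a median log2 fold change of -0.37 (camera adjusted p = 2.18e-07, and adjusted p = 0.525 with an estimated correlation). Insig1 stood at 122.6 ± 2.09 CPM against 198.7 ± 6.83 CPM in OHSS (SD, n = 2; log2 -0.70, SE 0.115), and Msmo1 at 218.5 ± 7.04 against 337.8 ± 26.4 CPM (-0.63, SE 0.116). The nintedanib mean lay between the COH and OHSS means for 18 of the 21 genes, and both nintedanib libraries did so for 9. Both counts rest on the OHSS libraries that showed the rise, and no value for unchanged groups stands beside them. They therefore do not measure a return toward COH. Of the 21 members edgeR called 0 over all genes, 8 adjusted over the list alone and 10 at an unadjusted p under 0.05, DESeq2 called 5 and limma voom 0. Mitochondrial transcripts fell, with 13 of 13 lower and a median of -0.37 (camera adjusted p = 2.18e-07, and adjusted p = 0.525 with an estimated correlation), for example mt-Nd1, a complex I subunit, at -0.64 (SE 0.173) and mt-Atp8 at -0.42 (SE 0.135). Luteal cell markers fell, with 10 of 12 lower and a median of -0.39 (camera adjusted p = 0.00946, and adjusted p = 0.502 with an estimated correlation). Sfrp4 among them averaged 3361 ± 385 against 6837 ± 2700 CPM (log2 -1.02, SE 0.296), and Idh1, which supplies NADPH, differed by -0.46 (SE 0.175). The luteal call was lost without nintedanib replicate 2 (camera adjusted p = 0.0567, range over the alternatives 0.0115 to 0.0567). At an unadjusted p under 0.05 edgeR had 4 mitochondrial and 2 luteal genes, with 0 called over all genes by edgeR or limma voom, and DESeq2 called 1 and 0.

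Endothelial cell markers rose with nintedanib, with higher means for 19 of 20 members and a median log2 fold change of 0.27 (camera adjusted p = 0.000104, and adjusted p = 0.502 with an estimated correlation). Tie1 averaged 72.5 ± 3.67 CPM against 52.5 ± 2.16 CPM in OHSS (SD, n = 2; log2 0.47, SE 0.101), Cdh5, the cadherin of endothelial junctions, 192.3 ± 20.3 against 128.2 ± 9.66 CPM (0.59, SE 0.129), and Vwf, the clotting carrier protein, 17.2 ± 6.22 against 7.16 ± 0.651 CPM (1.26, SE 0.333). VEGF and angiopoietin ligands and receptors rose, with 12 of 14 higher and a median of 0.28 (camera adjusted p = 0.00257, and adjusted p = 0.502 with an estimated correlation), Tie1 and Tek, the angiopoietin receptor, among them, the latter at 0.40 (SE 0.109). This list shares Kdr, Tek and Tie1 with the endothelial list, so their calls are not separate evidence. The VEGF and angiopoietin call was lost without OHSS replicate 2 or nintedanib replicate 1. The median was 0.17 without nintedanib replicate 1. Of these 14 members edgeR called 0 over all genes and limma voom 0, with 2 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 1. The target kinases of nintedanib were not called, with 6 of 12 higher and a median of 0.08 (camera adjusted p = 0.711). Kdr, Flt1 and Flt4 differed by 0.26 (SE 0.132), 0.19 (SE 0.146) and 0.29 (SE 0.142), Pdgfra and Pdgfrb by -0.24 and -0.22, Fgfr1 and Fgfr2 by -0.06 and -0.38, and Fgfr3 by -0.57 (SE 0.463). Vegfa stood at 127.4 ± 9.51 CPM (log2 -0.13, SE 0.211), and Pecam1 differed by 0.14. EdgeR called 0 members of the endothelial list over all genes and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. Vessel barrier genes (median 0.11, camera adjusted p = 0.25), endothelial tip genes (0.08, 0.442) and lymphatic endothelial markers (-0.01, 0.772) were not called. With 1 library left out their medians ran from 0.014 to 0.18, -0.069 to 0.23 and -0.15 to 0.11, and that of the target kinases from -0.025 to 0.18. The sign turned without nintedanib replicate 1 for the kinase and tip lists, without OHSS replicate 2 for the tip and lymphatic lists and without nintedanib replicate 2 for the lymphatic list, and without nintedanib replicate 2 camera called the tip list as higher.

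Macrophage and monocyte markers fell with nintedanib, with 13 of 14 lower and a median log2 fold change of -0.34 (camera adjusted p = 0.000743, and adjusted p = 0.525 with an estimated correlation). Lyz2, the lysozyme of macrophages, averaged 66.5 ± 22.2 CPM against 152 ± 20.7 CPM in OHSS (SD, n = 2; log2 -1.19, SE 0.249), and Csf1r, their growth factor receptor, differed by -0.47 (SE 0.143). Adipocyte markers fell, with 7 of 7 lower and a median of -0.66 (camera adjusted p = 0.0498, and adjusted p = 0.633 with an estimated correlation), Car3, a carbonic anhydrase abundant in fat, among them at -3.14 (SE 1.1). Interferon response genes rose, with 14 of 14 higher and a median of 1.07 (camera adjusted p = 0.00493, and adjusted p = 0.868 with an estimated correlation), for example Oasl2 at 195.3 ± 31.0 against 108.4 ± 54.2 CPM. Oocyte markers rose, with 17 of 18 higher and a median of 0.44 (camera adjusted p = 0.047, and adjusted p = 0.945 with an estimated correlation), Oog1 among them at 0.73 (SE 0.311). Without OHSS replicate 1 the calls of the macrophage (camera adjusted p = 0.399), adipocyte (0.0861) and oocyte lists (0.399) were lost, and without OHSS replicate 2 those of the adipocyte (0.278) and interferon lists (0.798). The interferon and oocyte lists lost theirs without nintedanib replicate 2 (camera adjusted p = 0.623 and 0.151), where the oocyte direction turned to lower, and the adipocyte list without nintedanib replicate 1 (0.555). Over the alternatives the adjusted p spanned 4.19e-06 to 0.399 for macrophage, 0.000991 to 0.555 for adipocyte, 4.22e-07 to 0.798 for interferon and 6.81e-06 to 0.399 for oocyte markers. No member of the interferon (0 of 14) or oocyte list (0 of 18) was at an unadjusted p under 0.05 by edgeR, and 0 were called by edgeR, DESeq2 or limma voom. The oocyte medians of the nintedanib libraries lay on both sides of the COH mean, at -0.71 and 0.46, against -0.57 and -0.35 in OHSS. The adipocyte medians were -2.09 and 0.02 with nintedanib against -0.23 and 0.79 in OHSS, so nintedanib replicate 2 lay between the OHSS libraries. With libraries left out the median log2 fold change of the adipocyte list was -1.40 (OHSS replicate 1), -0.22 (OHSS replicate 2) and -5.85 (nintedanib replicate 2), and that of the macrophage list -0.17 (OHSS replicate 1) and -0.66 (OHSS replicate 2). The -5.85 is a fitted value from 1 nintedanib library, whose median in log2 CPM lay at -2.09, so its size is uncertain. The median log2 fold change of the oocyte list was 0.83 without nintedanib replicate 1 and -0.10 without nintedanib replicate 2. For the interferon list it was 2.74 and 0.40 without OHSS replicates 1 and 2, and 1.68 and -0.47 without nintedanib replicates 1 and 2, so the sign of its median turned without nintedanib replicate 2. EdgeR had 2 macrophage and 1 adipocyte genes at an unadjusted p under 0.05 and called 0 over all genes, limma voom called 0, and DESeq2 called 1 and 0.

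Among the steroid genes with nintedanib, Cyp19a1 stood at 91.9 ± 42.1 CPM against 40.3 ± 1.75 CPM in OHSS (SD, n = 2; log2 1.19, SE 0.366), and Cyp17a1 at 1599 ± 1220 against 1048 ± 258 CPM (0.61, SE 0.641). Star, Cyp11a1 and Lhcgr differed by -0.25 (SE 0.333), -0.31 and -0.27, and the steroid hormone synthesis list was not called (median -0.15, camera adjusted p = 0.749). Pgr stood at 5.96 ± 0.292 CPM (log2 -1.33, SE 0.218) and Ptx3 at 3.56 ± 0.663 CPM (1.31, SE 0.31). The ovulation list was not called (median 0.06, camera adjusted p = 0.94), with 1 member, Pgr, called when adjusted over the list alone. Ace, the angiotensin converting enzyme, stood at 42.4 ± 3.55 against 23.6 ± 1.95 CPM (0.84, SE 0.138), while the renin angiotensin list was not called (median -0.34, camera adjusted p = 0.909), with Ace its 1 member called when adjusted over the list alone. Ctgf, a matrix protein of fibrosis, stood at 126.8 ± 42.5 against 58.3 ± 1.74 CPM (1.12, SE 0.233), while the extracellular matrix list was not called (median 0.01, camera adjusted p = 0.856). Immediate early and heat shock genes had a median of 0.41 (camera adjusted p = 0.0612), beside the called fall of the mitochondrial transcripts, the other list fixed as a sign of RNA quality and handling. The library medians of the immediate early list were -0.93 and 0.53 with nintedanib against -0.95 and -0.52 in OHSS, and without nintedanib replicate 2 the median log2 fold change turned to -0.04. Without OHSS replicate 1 it was 0.28 and without nintedanib replicate 1 it was 0.70. Neutrophil markers had a median of -0.64 (camera adjusted p = 0.0518), which was 0.43 without OHSS replicate 2 and -1.17 without OHSS replicate 1. The steroid median turned to 0.23 without OHSS replicate 1 and 0.027 without nintedanib replicate 2 (lowest -0.29), the renin angiotensin median to 0.10 without OHSS replicate 1 (lowest -0.56) and the ovulation median to -0.24 without nintedanib replicate 2 (highest 0.37), while the extracellular matrix median ran from 0.00079 to 0.050. With a library left out camera also called neutrophil markers as lower (without OHSS replicate 1), erythroid markers as higher (without OHSS replicate 2), immediate early genes as higher (without OHSS replicate 2 or nintedanib replicate 1), ovulation genes as higher (without nintedanib replicate 1) and surface epithelium markers as lower (without nintedanib replicate 2). The other uncalled lists with nintedanib had camera adjusted p of 0.173 to 0.94. Among the uncalled lists the median and the camera direction differed in sign for 7: lymphatic, stromal and theca, surface epithelium, ovulation, inflammatory, extracellular matrix and renin angiotensin.

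Rpsa-ps10 (ENSMUSG00000047676), annotated as a pseudogene of the ribosomal protein gene Rpsa, was the only gene edgeR called in nintedanib against OHSS. It was chosen after its values were seen, since the naming rule leaves pseudogenes out. It rose from 7.29 ± 2.1 to 359.8 ± 19.4 CPM (SD, n = 2), a log2 fold change of 5.62 (SE 0.243, edgeR adjusted p = 0.0241), in both libraries. Rpsa itself stood at 619.1 ± 5.20 CPM against 814.7 ± 126 CPM in OHSS, and reads of the pair may be split between the copies, so both levels are uncertain. EdgeR called 1 gene higher and 0 lower, with 1412 at an unadjusted p under 0.05, 751 higher and 661 lower, where 951 would be expected by chance. The groups did not overlap for 36.2% of genes against 33.3% by chance. DESeq2 called 213 genes, 108 higher and 105 lower, and limma voom called 1. This comparison holds no COH library, so leaving one out changes only the filter, the scaling and the fit of the test. Without COH replicate 1 or COH replicate 2 edgeR called 0 genes, with 1060 and 1051 at an unadjusted p under 0.05. Without OHSS replicate 1 or nintedanib replicate 2 it called 2, without OHSS replicate 2 it called 1, and without nintedanib replicate 1, where the outlying replicate 2 alone stands for the drug, it called 30. Rpsa-ps10 missed the threshold without COH replicate 1 (edgeR adjusted p = 0.316), COH replicate 2 (0.265) or nintedanib replicate 2 (0.0661), over a range of 0.0204 to 0.316 with each library left out, while its log2 fold change stayed between 5.36 and 5.93. Of the 29 lists 11 were called, 6 higher and 5 lower, and 0 with an estimated correlation or by the directional fry test. The mixed fry test called 5: VEGF and angiopoietin (fry adjusted p = 0.0182), endothelial (0.0182), cholesterol (0.0182), ovulation (0.00991) and extracellular matrix (0.036). Over the 364 tested list genes edgeR called 0 and limma voom 0, with 64 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 14, 5 of them higher. The cell cycle, cholesterol, mitochondrial, granulosa and endothelial lists kept their calls with each library left out in turn.

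**Figure D1:**
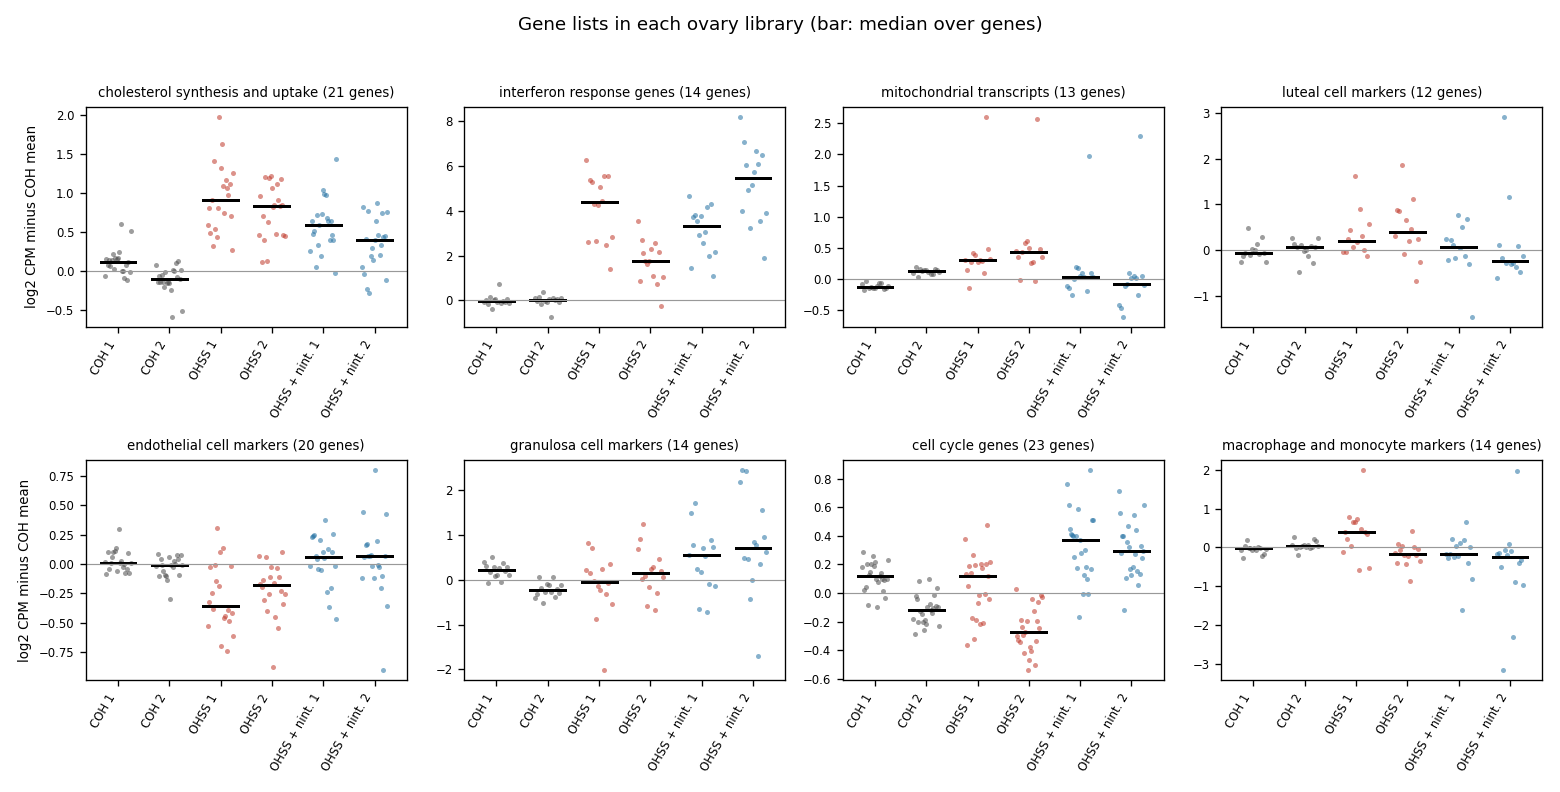
Each panel shows 1 gene list, with points for its genes as log2 CPM in a library minus the mean of the COH libraries and a bar at the library's median. The interferon medians of the OHSS libraries sit at 4.37 and 1.76 and those of the nintedanib libraries at 3.30 and 5.43, while the cholesterol medians sit at 0.91 and 0.83 in OHSS and 0.58 and 0.39 with nintedanib.

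OHSS with nintedanib against COH asks which differences from the COH ovaries are present under the drug. Interferon response genes rose, with higher means for 14 of 14 members and a median log2 fold change of 4.85 (camera adjusted p = 3.26e-11, and adjusted p = 0.808 with an estimated correlation). Oasl2 averaged 195.3 ± 31.0 CPM against 23.0 ± 0.69 CPM in COH (SD, n = 2; log2 3.09, SE 0.376), Oas1a differed by 4.66 (SE 0.993), and Ifit1, an antiviral RNA-binding protein, by 7.35 (SE 1.69). Cholesterol synthesis and uptake genes rose, with 19 of 21 higher and a median of 0.44 (camera adjusted p = 1.72e-06, and adjusted p = 0.808 with an estimated correlation). Idi1 among them stood at 171.3 ± 4.48 against 103.3 ± 14.1 CPM (0.73, SE 0.139). Granulosa cell markers rose, with 12 of 14 higher and a median of 0.64 (camera adjusted p = 0.000894, and adjusted p = 0.808 with an estimated correlation), Inhba among them at 2.11 (SE 0.318) and Nr5a2 at 0.77 (SE 0.185). Cell cycle genes rose, with 22 of 23 higher and a median of 0.32 (camera adjusted p = 4.28e-05, and adjusted p = 0.808 with an estimated correlation), for example Mki67, a marker of dividing cells, at 0.73 (SE 0.18) and Ccnb1 at 0.37 (SE 0.12). Macrophage and monocyte markers fell, with 12 of 14 lower and a median of -0.20 (camera adjusted p = 0.0204, and adjusted p = 0.808 with an estimated correlation). Lyz2 stood at 66.5 ± 22.2 against 250.8 ± 16 CPM (-1.92, SE 0.254), and Ccr2, a monocyte chemokine receptor, differed by -0.92 (SE 0.23). The granulosa call was lost without COH replicate 2 (camera adjusted p = 0.0642, range over the alternatives 3.53e-05 to 0.0642), and the macrophage call without COH replicate 2 (0.12) or nintedanib replicate 2 (0.188, range 0.0082 to 0.188). The macrophage median was -0.13 without COH replicate 2, and the interferon median 3.22 without nintedanib replicate 2.

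Among the members of these lists in nintedanib against COH, edgeR called 0 over all genes and limma voom 0. Adjusted over the list alone edgeR called 14 interferon, 5 cholesterol, 7 granulosa, 0 cell cycle and 1 macrophage genes, with 14, 11, 8, 4 and 2 at an unadjusted p under 0.05, and DESeq2 called 12, 4, 6, 1 and 2. Endothelial cell markers, 12 of 20 higher, had a median of 0.05 (camera adjusted p = 0.698), the VEGF and angiopoietin list 0.18 (0.0943), and vessel barrier genes 0.02 (0.93). Kdr, Flt1, Cdh5 and Vegfa differed by 0.15, 0.34 (SE 0.146), 0.34 (SE 0.129) and 0.40 (SE 0.211), and Flt4 and Pecam1 by 0.21 (SE 0.142) and -0.07 (SE 0.202). Pdgfra and Pdgfrb differed by -0.32 (SE 0.16) and -0.55 (SE 0.248), and Fgfr1, Fgfr2 and Fgfr3 by -0.11 (SE 0.183), -0.12 (SE 0.295) and -0.67 (SE 0.463). Aqp1, a water channel of vessel walls on the barrier list, stood at 23.6 ± 2.55 CPM against 47.2 ± 8.10 CPM in COH (SD, n = 2), with an SE of 0.227 on the log2 scale. Steroid hormone synthesis had a median of 0.16 (camera adjusted p = 0.198), with Star at 0.98 (SE 0.336), Cyp17a1 at 2.25 (SE 0.669), Cyp19a1 at 2.02 (SE 0.376), Cyp11a1 at -0.12 (SE 0.186) and Lhcgr at -0.14 (SE 0.337). Ctgf differed by 1.68 (SE 0.237) and Ace by 0.73 (SE 0.138), and Cyp19a1, Ctgf and Ace were each the 1 member of their list called when adjusted over the list alone, with 2 in the inflammatory list. Mitochondrial transcripts had a median of 0.02 (camera adjusted p = 0.93), luteal cell markers of -0.09 (0.764) and the target kinases of -0.12 (0.665). Among the mitochondrial transcripts mt-Atp6 differed by 2.13 (SE 0.19), the 1 member called by edgeR when adjusted over the list alone. The other uncalled lists against COH had camera adjusted p of 0.083 to 0.93. Median and camera direction differed in sign for the vessel barrier, stromal and theca, luteal, oviduct and mitochondrial lists. With 1 library left out the medians ran from 0.037 to 0.11 for endothelial, 0.14 to 0.24 for VEGF and angiopoietin, -0.090 to 0.13 for vessel barrier, 0.090 to 0.35 for steroid, -0.11 to 0.093 for mitochondrial, -0.24 to 0.059 for luteal and -0.20 to 0.043 for target kinase genes. The sign turned without COH replicate 2 for the barrier and luteal lists, without COH replicate 1 for the mitochondrial and kinase lists, without nintedanib replicate 2 for the barrier and luteal lists and without nintedanib replicate 1 for the mitochondrial list. Without nintedanib replicate 2 camera also called the VEGF and steroid lists as higher and the immediate early, oocyte and surface epithelium lists as lower, and without nintedanib replicate 1 the ovulation list as higher and the tip and erythroid lists as lower. Without COH replicate 2 it called the inflammatory list as higher and the oocyte and surface epithelium lists as lower, and without either OHSS library the erythroid list as lower.

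As single genes, Tmem170b, Ak4, Fggy and Rpsa-ps10 rose and Aldh3b2 fell in nintedanib against COH. Tmem170b stood at 37.4 ± 2.44 CPM (SD, n = 2; log2 4.95, SE 0.171, edgeR adjusted p = 0.00729) and Ak4 at 14.7 ± 0.282 CPM (3.19, SE 0.167, 0.0222), against 1.21 and 1.61 CPM in COH. Fggy (ENSMUSG00000028573), a carbohydrate kinase, stood at 22.01 ± 2.82 against 3.47 ± 0.25 CPM (log2 2.67, SE 0.169, edgeR adjusted p = 0.0379). Ak4 and Fggy lie on the same chromosome with 23 places between their ranks among tested genes. Aldh3b2 (ENSMUSG00000075296), an aldehyde dehydrogenase of lipid metabolism, had 367 and 255 counts in COH, 465 and 364 in OHSS, and 0 and 1 with nintedanib (edgeR adjusted p = 0.0358). Taking 2 counts as 1 read pair and the single count as 1 pair, its COH level was 293 times that with nintedanib, with a counting interval of 52.6 to 11600 that covers counting error only. Rpsa-ps10 stood at 359.8 against 11.5 CPM (log2 4.97, SE 0.235, edgeR adjusted p = 0.0194), and its reads share the doubt named above for Rpsa. For all 5 genes the libraries of the 2 groups did not overlap.

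EdgeR called these 5 genes, 4 higher and 1 lower, in nintedanib against COH, with 1845 at an unadjusted p under 0.05, 1069 higher and 776 lower, where 951 would be expected by chance. The groups did not overlap for 45.0% of genes against 33.3% by chance. DESeq2 called 436 genes, 311 higher and 125 lower, and limma voom called 2, Tmem170b and Rpsa-ps10. Without COH replicate 1 or COH replicate 2 edgeR called 0 genes, with 1260 and 862 at an unadjusted p under 0.05. Without OHSS replicate 2 it called 2, without nintedanib replicate 2, the library that stands apart, it called 3, and without nintedanib replicate 1, where replicate 2 alone stands for the drug, it called 53. With each library left out the log2 fold changes stayed between 4.85 and 5.05 for Tmem170b, 3.17 and 3.21 for Ak4, 2.53 and 2.79 for Fggy and 4.92 and 5.03 for Rpsa-ps10. That of Aldh3b2 moved between -11.22 and -8.10, a fitted value that depends on the prior count at 0 and 1 counts and is no bound. Without COH replicate 1 or COH replicate 2 the edgeR adjusted p was 0.126 and 0.223 for Tmem170b, 0.191 and 0.266 for Ak4, 0.242 and 0.297 for Fggy, 0.191 and 0.266 for Aldh3b2 and 0.191 and 0.266 for Rpsa-ps10. Without nintedanib replicate 2 it was 0.0644 for Ak4, 0.0933 for Fggy, 0.0572 for Aldh3b2 and 0.0572 for Rpsa-ps10, and without OHSS replicate 1 or OHSS replicate 2 it was 0.0975 and 0.0961 for Ak4, 0.104 and 0.111 for Fggy and 0.103 and 0.0968 for Aldh3b2. Over the 6 libraries left out the lowest edgeR adjusted p was 0.016 for Tmem170b, 0.0266 for Ak4, 0.0266 for Fggy, 0.0262 for Aldh3b2 and 0.0129 for Rpsa-ps10. Of the 29 lists 5 were called, 4 higher and 1 lower, and 0 with an estimated correlation or by the directional fry test. The mixed fry test called 6: stromal and theca (fry adjusted p = 0.00832), macrophage (0.0255), oviduct (0.0255), cholesterol (0.0255), inflammatory (0.00832) and mitochondrial (0.00832). Over the 364 tested list genes edgeR called 0 and limma voom 0, with 71 at an unadjusted p under 0.05 by edgeR, and DESeq2 called 34, 29 of them higher. Without nintedanib replicate 1 the number of lists called was 8 and without nintedanib replicate 2 it was 9.

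**Figure D2:**
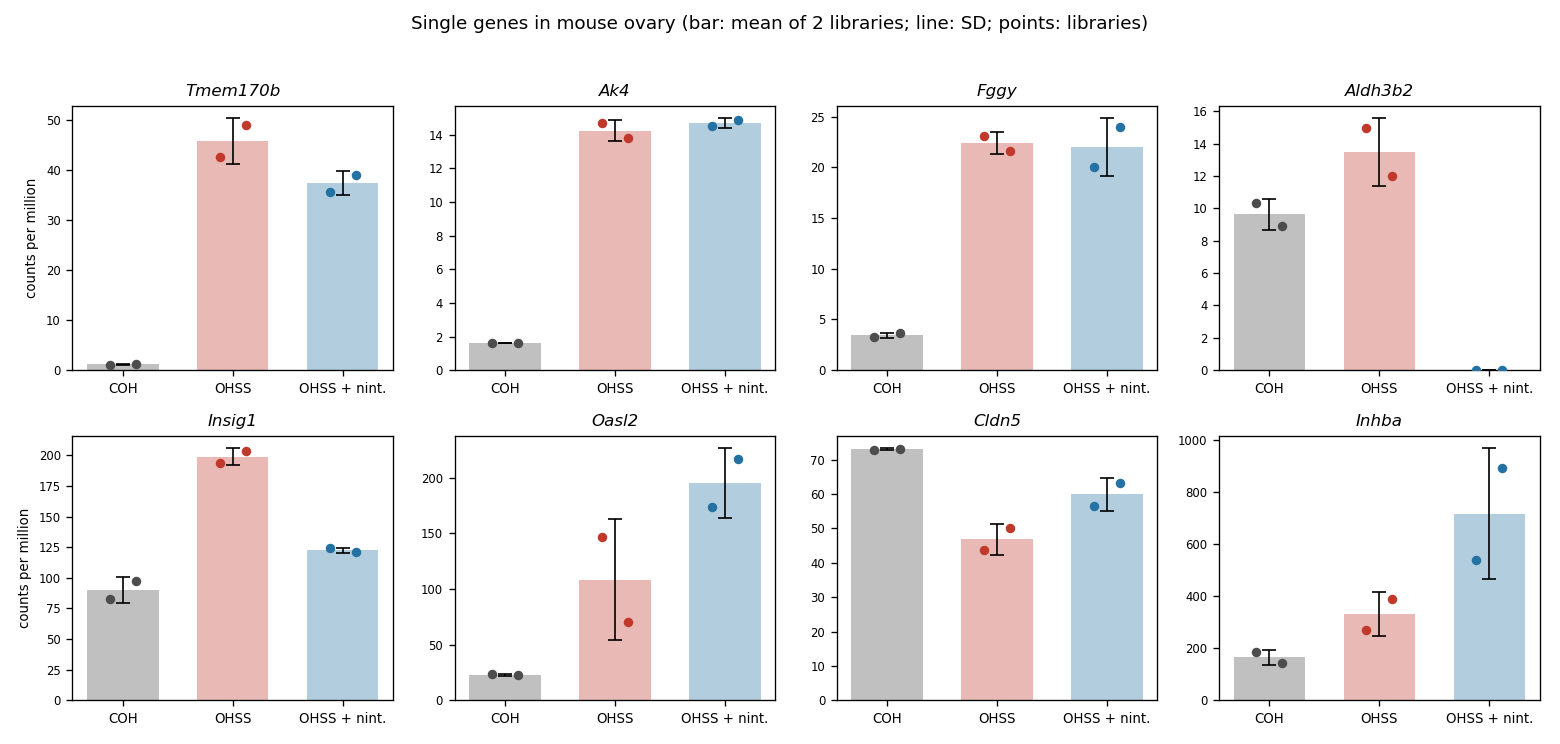
Bars give the mean CPM of 8 named genes in the COH, OHSS and nintedanib groups, error bars the SD and points the 2 libraries of each group. Tmem170b averages 1.21 CPM in COH against 45.8 in OHSS and 37.4 with nintedanib, and Aldh3b2 averages 13.5 CPM in OHSS and 0.0156 with nintedanib.

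The design also asks how far the nintedanib libraries lie back toward COH. Of the 2 genes called in OHSS against COH, Tmem170b had the opposite sign in nintedanib against OHSS (log2 -0.29) and Ak4 the same sign (0.04), which gives 50%. Without OHSS replicate 1, where 2 genes were called, the share was 100%, and with any other library left out no gene was called and there was no share. Among the 1679 genes at an unadjusted p under 0.05, 1373 or 81.8% had the opposite sign, but both comparisons hold the OHSS libraries, and simulated libraries with no difference gave 87.6% (83.5 to 90.2 over 20 draws). Across genes, which are not independent replicates, the correlation of the log2 fold changes was -0.40, against -0.50 in the simulation (-0.54 to -0.46). It was -0.28 without COH replicate 1, -0.62 without OHSS replicate 1 or OHSS replicate 2, and -0.30 without nintedanib replicate 1. The covariance was -0.201 against a simulated -0.167 (-0.193 to -0.155), a difference of -0.0341. At an unadjusted p under 0.05, 188 genes were higher in OHSS and lower with nintedanib, where independent lists give 30.3 and the simulation 81.2 (65 to 93), and 184 were lower and then higher, against 31.8 and 134 (105 to 158). The simulation had only 877 genes (828 to 915) at that p in OHSS against COH. As a share of the genes higher in OHSS the 188 make 21.5%, against 18.8% simulated (15 to 22.2), and the 184 make 22.8% of the genes lower in OHSS, against 30.1% (26.2 to 35). In the same direction in both, 15 were higher and 10 lower, against 34.5 and 28 for independent lists and 2.65 (0 to 7) and 3.75 (1 to 7) simulated. The simulation leaves out real effects and the independent value leaves out the shared libraries, so the excess over either does not decide whether there is a shared effect. No split of the 2 OHSS libraries leaves 2 for each comparison, and part of the excess may come from the shared libraries. Of the 11 lists called in each comparison 6 were called in both, where independent calls give 4.17, and 5 of them in opposite directions: cholesterol, mitochondrial, endothelial, luteal and oocyte. Called or not, camera's direction was opposite for 22 of the 29 lists, and for 19.6 (15 to 23) in the simulation, so opposite directions alone are what the shared libraries give. The simulation called 0 lists in both (0 to 0), but it draws genes independently and so leaves out their correlation within a list.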

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

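The robust prior and the DESeq2 versions of the opposite-sign share and of the correlation were chosen after the data had been seen, and the robust prior left the gene counts at 2, 1 and 5. For 125 gene results named in the text, 1869 of 1999 values under 16 other settings kept their direction and their side of the threshold, 51 lost a call, 50 gained one (47 of them with DESeq2) and 29 changed sign, each in a gene that was not called. Only a called gene can lose a call, and most of the 125 results were not called. The 1869 values therefore say little about how stable the calls are. The number of genes called in OHSS against COH, nintedanib against OHSS and nintedanib against COH was 348, 213 and 436 with DESeq2, 0, 1 and 2 with limma voom, 4, 2 and 6 with no low count filter, and 0, 0 and 2 in a fit of only the 2 groups compared. That fit has fewer residual degrees of freedom, and had 1864, 1023 and 1967 genes at an unadjusted p under 0.05, against 1585, 1355 and 1767 with limma voom. Other scalings, a stricter filter and a fold threshold left the counts at 2, 1 and 5. With each library left out the counts ranged from 0 to 2, 0 to 30 and 0 to 53, and those of called lists from 6 to 12, 9 to 11 and 5 to 9. The stricter filter ended the calls of the endothelial tip list in OHSS against COH (camera adjusted p = 0.0844, range 0.0447 to 0.185) and of the adipocyte and oocyte lists in nintedanib against OHSS (0.0614, range 0.000991 to 0.555, and 0.0579, range 6.81e-06 to 0.399), and RLE scaling that of the adipocyte list (0.0569). An estimated correlation gave 0, 0 and 0 lists and the directional fry test 0, 0 and 0. The opposite-sign share was 75% with no low count filter, 77.9% with DESeq2 and 100% without OHSS replicate 1, the only library whose removal left a value. The correlation ranged from -0.62 to -0.28 with each library left out. Replicate numbers are shared by the groups, and the titles do not say whether they pair the libraries. Same-numbered libraries did not deviate together across genes (correlations of -0.00072, 0.048 and -0.0023), which gives no sign of pairing but could miss a weak one. Of the called genes, only Tmem170b kept its calls under a replicate block, while Ak4, Fggy, Aldh3b2 and Rpsa-ps10 lost theirs. With a replicate block edgeR called 1, 0 and 2 genes, with 1474, 1242 and 1623 at an unadjusted p under 0.05, and 9, 12 and 5 lists, without the luteal (camera adjusted p = 0.0615, range 0.028 to 0.262) and endothelial tip lists (0.0648, range 0.0447 to 0.185) in OHSS against COH and the oocyte list in nintedanib against OHSS (0.0617, range 6.81e-06 to 0.399), where the immediate early and neutrophil lists were added (0.0288, range 3.31e-05 to 0.833, and 0.0451, range 0.000688 to 0.798), and the share was 100% (1 of 1 gene). Sign changes with a library left out came with these ranges of log2 fold change in OHSS against COH: Flt4 -0.23 to 0.063, Pdgfra -0.24 to 0.075, Fgfr1 -0.28 to 0.14, Fgfr2 -0.20 to 0.61, Fgfr3 -0.63 to 0.76, Pecam1 -0.54 to 0.078 and Lhcgr -0.11 to 0.40. In nintedanib against OHSS they were Vegfa -0.39 to 0.18, Pdgfrb -0.56 to 0.052, Fgfr1 -0.25 to 0.16, Fgfr2 -0.73 to 0.077, Pecam1 -0.15 to 0.46, Star -0.66 to 0.29, Cyp17a1 -0.52 to 1.23 and Lhcgr -0.77 to 0.10, and in nintedanib against COH Fgfr1 -0.25 to 0.0062, Fgfr2 -0.34 to 0.073, Fgfr3 -1.21 to 0.19, Cyp11a1 -0.32 to 0.046 and Lhcgr -0.65 to 0.23. Fgfr3 in OHSS against COH was 0.019 under the block and 0.0061 with limma voom, and Fgfr1 in nintedanib against OHSS 0.018 with library size only. For these changes the cause was not tested, apart from the fewer libraries in the fits named. With 2 libraries per group the simulated test missed most genes changed 2-fold, which limits what an uncalled gene shows. Larger differences also went uncalled in OHSS against COH, such as the 14 interferon response genes with a median log2 fold change of 3.51.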

Other observations

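The pathway tests, the length-matched sets and the tests on Rpsa, the interferon genes and mt-Atp6 were chosen after the results were seen, while those on overlapping and neighbouring genes were set out before. Of 297 pathways in the table's own annotation, camera called 8 in OHSS against COH, 5 in nintedanib against OHSS and 5 in nintedanib against COH, and 0 in each with an estimated correlation. The ribosome stood out in OHSS against COH, where its genes fell: 130 of 133 were lower, with a median log2 fold change of -0.41 (camera adjusted p = 3.24e-25, and adjusted p = 1 with an estimated correlation). It held its call without any 1 library, with camera adjusted p of 9.81e-27 to 9.65e-12. The 81 proteins of the cytosolic ribosome had a median of -0.46, with 81 of 81 lower, and the 42 of the mitochondrial ribosome a median of -0.21. Rpl30 stood at 72.7 ± 3.29 CPM in OHSS and 194.3 ± 1.02 CPM in COH (SD, n = 2; log2 -1.42, SE 0.188), Rps28 at 152.1 ± 13.7 against 236.5 ± 0.187 CPM and Rpl39 at 136.9 ± 20.5 against 220.9 ± 1.41 CPM, all chosen after their values were seen. Such genes have many pseudogene copies, and their levels are uncertain. The pathway was also lower in nintedanib against COH (121 of 133, median -0.29, camera adjusted p = 1.37e-13, and adjusted p = 0.991 with an estimated correlation). In nintedanib against OHSS it rose, with 108 of 133 higher and a median of 0.13 (camera adjusted p = 0.023, and adjusted p = 0.988 with an estimated correlation), a call lost without COH replicate 2 (0.0521), OHSS replicate 2 (0.872), nintedanib replicate 1 (0.126) or nintedanib replicate 2 (0.21), over a range of 1.02e-05 to 0.872. The directions were the same with TMM, RLE, upper quartile and library size scaling. Ribosomal transcripts are short, with a median of 1120 bases against 2963 for all tested genes, and 1000 random sets matched on expression and length had a median of -0.08 (-0.13 to -0.02) in OHSS against COH and -0.13 (-0.18 to -0.07) in nintedanib against COH.

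Oxidative phosphorylation genes fell in OHSS against COH, with 90 of 124 lower and a median log2 fold change of -0.20 (camera adjusted p = 0.012, and adjusted p = 1 with an estimated correlation), and medians of -0.15 and -0.26 in the 2 OHSS libraries. The pathway includes 13 mitochondrial transcripts, which as a list moved the other way. Random sets matched on expression and length had a median of -0.12 (-0.17 to -0.06), so part of the fall goes with transcript length or expression. The call was lost without COH replicate 2 (camera adjusted p = 0.632) or OHSS replicate 2 (0.453), over a range of 0.00221 to 0.632. In nintedanib against COH 100 of 124 were lower, with a median of -0.17 (camera adjusted p = 0.00047, and adjusted p = 0.991 with an estimated correlation), inside the range of matched sets (-0.18 to -0.08). That call was lost without COH replicate 2 (camera adjusted p = 0.481) or nintedanib replicate 2 (0.321), over a range of 0.000174 to 0.481.

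Genes for the biosynthesis of unsaturated fatty acids rose in OHSS against COH, with 21 of 27 higher and a median log2 fold change of 0.25 (camera adjusted p = 0.0281, and adjusted p = 1 with an estimated correlation). Scd1, the desaturase that makes oleate, stood at 384.2 ± 19.9 against 142.2 ± 23.5 CPM in COH (SD, n = 2; log2 1.43, SE 0.278), and Hsd17b12, an enzyme of fatty acid elongation, at 159.4 ± 14.8 against 50.4 ± 4.51 CPM (1.66, SE 0.216), both chosen after their values were seen. The call was lost without COH replicate 1 (camera adjusted p = 0.077), COH replicate 2 (0.304), OHSS replicate 1 (0.203) or OHSS replicate 2 (0.0796), over a range of 0.0115 to 0.304. Mgarp, a mitochondrial protein of steroid-making tissue chosen after its values were seen, stood at 737 ± 5.64 CPM in COH, 118.3 ± 52.5 in OHSS and 647.7 ± 167 with nintedanib, and was not called (edgeR adjusted p = 0.242 and 0.414). Pcdhb19, also chosen after its values were seen, had 261 and 280 counts in COH, 188 and 314 in OHSS, and 0 and 0 with nintedanib, at least 41.5-fold lower than in OHSS at a floor of 3 read pairs (6 counts) per library, and was not called (edgeR adjusted p = 0.12).

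The genes that separate the groups most sharply, such as Tmem170b, Ak4, Fggy, Aldh3b2 and Rpsa-ps10, form the first pattern that was weighed. Shared reads between overlapping gene models could produce such genes: 35.8% of the 109 genes at an unadjusted p under 0.001 overlap another tested gene, between the median of random sets (33%) and the upper end of their 95% range (41.3%), so this cannot be told apart from chance. ICR mice are outbred, and inherited differences shared by the libraries of a group would place such genes near each other: 5 neighbouring pairs were found against a random median of 3 and an upper end of 7, which decides nothing either. Pairs were counted only within 5 tested genes, so Ak4 and Fggy, 23 ranks apart on the same chromosome, could not be counted. For Rpsa-ps10, reads may have moved from the parent gene. The Rpsa mean with nintedanib minus that in OHSS was -195.6 CPM, while Rpsa-ps10 was 352.5 CPM higher. Their sum was 156.9 CPM higher, less than the rise of Rpsa-ps10, and Rpsa was lower in both nintedanib libraries than in either OHSS library. A shift of reads would give both. The surplus in the sum is of the order of the SD of Rpsa in OHSS given above. In this comparison these means therefore cannot tell whether a shift covers all or part of the rise. Against COH, Rpsa was also lower with nintedanib (log2 -0.81, SE 0.143), and the sum was not compared there. An effect of the model or the drug on these genes stays open and untested.

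The spread of the interferon response genes is the second pattern. More macrophages and lymphocytes, with interferon genes at the same level per cell, might raise them, but the highest median of their 25 markers above the COH mean was 0.131, in OHSS replicate 1 (0.401 for the macrophage and monocyte markers alone), and the others were -0.217, -0.17 and -0.319, against interferon medians of 4.37, 1.76, 3.30 and 5.43. An effect of the model or the drug cannot be told apart from a difference between single animals or samples. The list's median differed by 2.61 between the 2 OHSS libraries and by 2.14 between the 2 nintedanib libraries, against group differences from COH of 3.06 and 4.36, although the lowest of the 4 libraries still lay 1.71 above the higher COH library. Activation of immune cells, few cells with very high interferon genes and a chance infection or exposure of some animals are candidate explanations that were not tested.

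The low mt-Atp6 level in both COH libraries is the last pattern. Against COH, mt-Atp6 was higher both in OHSS (log2 2.58) and with nintedanib (2.13, SE 0.19). Its reads could have gone to the identical nuclear copy Gm10925 in COH, but Gm10925 was lower there too, with a COH minus OHSS difference of -1089 CPM against an mt-Atp6 difference of 4494 CPM. A common change of the mitochondrial transcripts cannot account for it, since the other 12 had a median log2 fold change of 0.335 and a highest value of 0.497 against 2.58. A mitochondrial sequence variant carried by the COH animals stays open as a hypothesis, since the tables hold no reads to test it, and so does an effect of the model.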
